A study of Mus musculus with 11 samples.

How the data were processed

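Total RNA of epididymal fat from 4 wild-type, 4 B1 knockout and 3 fat rescue mice had been labelled and hybridized by the submitters to 1 one-colour Affymetrix mouse array per sample. The deposited table holds the authors' signal intensity per probe set, linear and not log-transformed, which the submitters' processing notes trace to GCOS 1.3 and MAS5. The mean of each array without the lowest and highest 2% of probe sets was 200, so the authors' software had scaled the arrays to a common level; the table holds no detection calls. Array medians differed by 0.241 on the log2 scale, less than the limit of 0.5 above which arrays would have been normalized further. A single value of 0 was set to the smallest positive value, 0.1, before log2 was taken.

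Of 45101 probe sets, 64 were controls, 34945 had 1 gene symbol, 932 had several and 9160 had none. The upper 60% of probe sets by mean log2 signal over all arrays were kept (27022), and each gene with 1 symbol was represented by its brightest kept probe set, which gave 12709 genes. Gene order on a chromosome was taken from a gene table of the mouse assembly GRCm38.p6, in which 12685 of these genes had a chromosome; the files name no genome build, so no coordinates are given.

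All 11 arrays were fitted in 1 linear model with limma 3.58.1 (eBayes with trend) in R 4.3.3, with statmod 1.5.0, and the genotype as the only factor. Each pair of genotypes was a contrast, two-sided, with Benjamini-Hochberg adjusted p under 0.05 over all genes, and a moderated F test covered the 3 genotypes. Bdkrb1 and Bdkrb2 were tested whatever their brightness, with adjustment over the 9 receptor tests, and with two-sided exact permutation tests on the log2 signals. Gene lists with at least 4 measured members were tested with camera at a preset correlation of 0.01, adjusted over the lists; of 32 lists 31 were tested, holding 727 genes, of which 656 were on the array and 561 measured. The list that was not tested, of the epididymis and male accessory glands, had 1 of 26 genes measured. Within a list, p was also adjusted over the list alone.

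Whether differences of the knockout run the other way in fat rescue was measured by Pearson's r across genes between 2 knockout arrays minus wild type and fat rescue minus the other 2 knockout arrays, averaged over the 6 divisions, beside 100 simulations with no effect. The comparisons, lists, tests and most alternatives, and the rule for genes named, were chosen before the data were examined. Genes named are Bdkrb1 and Bdkrb2; up to 12 genes in each direction with the largest differences among those past the threshold whose groups do not overlap; where fewer than 10 pass, the 6 in each direction with the smallest unadjusted p, given as not passing; and for each list described up to 4 members with the smallest unadjusted p and, for lists of other cell types, the 3 brightest. Not all genes that the rule allows are named.

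The alternatives were quantile normalization, centring on the array median, log2(value + 50), no filter on dim probe sets, the upper 40% of probe sets, all probe sets tested singly, the mean of a gene's probe sets, eBayes without trend, robust eBayes, array weights, fitting only the groups compared, the replicate number as a block, leaving out each array in turn, and for lists an estimated correlation, ranks and fry. Median centring of the lists, the fit without wild-type array 1 and rescue array 1, the comparison of both lines together with wild type, and cell-type list means as covariates were added after the data had been seen. The labels number the replicates of every genotype from 1 without saying that a number is shared by more than name, so the arrays were not treated as paired. The labels give no batch or scan date.

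The steps were tested on simulated data of the same size, with 200 of 12709 genes changed in 5 simulations. In knockout against wild type 44.8%, 74.6% and 91.5% of genes changed by a factor of 1.5, 2 and 4 were recovered, with 6.02% false calls. In fat rescue against knockout the shares were 36.4%, 66.3% and 93.0% (6.33% false), and in fat rescue against wild type 41.2%, 73.7% and 94.5% (6.94% false). With 200 changed genes the Benjamini-Hochberg threshold admits larger unadjusted p than when few genes change. In the arrays only 5, 0 and 2 genes passed in these comparisons. The shares are therefore too high for the arrays and do not tell how many single changes of these sizes were missed. Each comparison recovered 3 of 3 lists shifted by 0.3 on the log2 scale, and in knockout against wild type 1 other list also passed. The simulated genes were independent, whereas members of these lists were correlated in the arrays. Their estimated correlations were 0.72 for macrophage, 0.28 for endothelial and 0.46 for fatty acid oxidation genes. The simulation therefore cannot tell how camera's preset correlation performs on such lists.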

Results

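Gene expression was measured in epididymal fat, a visceral fat depot, of male C57BL/6 mice aged 3 months, with 11 one-colour Affymetrix arrays of 45101 probe sets each. Wild-type mice (B1+/+) gave 4 arrays. Knockout mice (B1-/-), which lack the kinin B1 receptor encoded by Bdkrb1, a G protein-coupled receptor for kinin peptides, gave 4 more. The last 3 came from fat rescue mice (aP2B1-B1-/-), in which the receptor is lacking except for expression in fat; aP2 is another name of the fatty acid binding protein gene Fabp4, whose promoter is used to drive transgenes in fat cells. The labels call the arrays of each genotype biological replicates, and they stand for separate animals only as far as these labels say. The median signal of an array lay between 41.3 and 45.1 in wild type, 46.5 and 48.8 in knockout, and 45.6 and 46.6 in fat rescue, at a trimmed mean of 200 in every array, and the number of arrays limits the precision of every comparison. Wild-type array 1 and rescue array 1 stood apart on the first principal component, which held 27.3% of the variance, at -45.4 and -34.1.

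The signal of Bdkrb1 itself was at or near background in wild-type and knockout fat and higher in fat rescue mice. Its only probe set read 12.6 ± 13.3 (SD, n = 4) in wild type, 17.7 ± 13.7 (n = 4) in knockout and 63.9 ± 8.36 (n = 3) in fat rescue, where each of the 3 arrays was above all 8 others. Rescue exceeded wild type by 2.86 ± 0.80 on the log2 scale (SE; adjusted p = 0.0250 over the 9 receptor tests; two-sided exact permutation p = 0.0571, where the smallest possible is 0.0286). Against knockout the difference was 2.28 ± 0.80 and missed the threshold (adjusted p = 0.0540; exact permutation p = 0.0857). Against signals this low neither difference is an exact size. With log2(value + 50) they were 0.88 and 0.77, and both passed (adjusted p = 0.00177 and 0.00292). Knockout and wild type differed by 0.58 ± 0.74, less than the spread between replicates (adjusted p = 0.685). Bdkrb2, which encodes the B2 receptor and lies beside Bdkrb1, did not pass in any comparison with either of its probe sets (adjusted p from 0.315 to 0.871). Where the probe set lies relative to the deleted sequence is not given, so the wild-type and knockout values do not check the genotype labels. The Bdkrb1 call against wild type was lost without wild-type array 1 (adjusted p = 0.0560) and without rescue array 1, 2 or 3 (0.108, 0.0754 and 0.0830), and that against knockout was reached without wild-type array 2 or 3 and without knockout array 2 or 4 (lowest adjusted p = 0.0266), and with median centring, robust eBayes and only the groups compared (0.0472, 0.0462 and 0.0232).

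**Figure D1:**
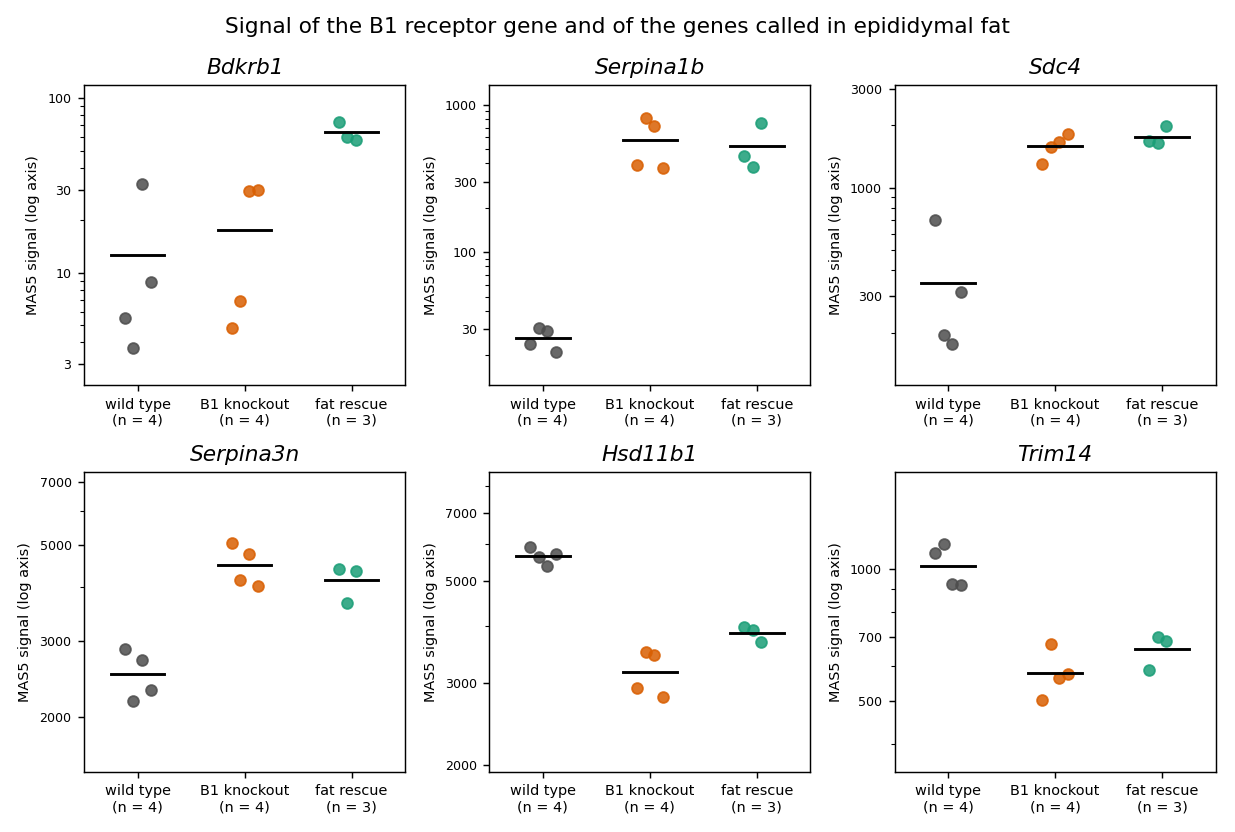
Probe-set signal (log scale) of Bdkrb1 and of genes that passed in a comparison, in each array of wild type (n = 4), knockout (n = 4) and fat rescue (n = 3); points are arrays and bars the group means. Bdkrb1 averaged 12.6, 17.7 and 63.9, and Serpina1b 26.1, 573 and 527.

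The comparison of knockout with wild type asks what the loss of the receptor goes with in fat. Serpina1b, one of the genes for the secreted protease inhibitor alpha-1-antitrypsin, rose from 26.1 ± 4.44 (SD, n = 4) to 573 ± 225 (n = 4), a log2 difference of 4.39 ± 0.28 (SE; adjusted p = 1.12e-05). Its wild-type signal was low, below the array medians, so this is no exact size; it ranged from 2.96 to 6.18 over the alternatives. Sdc4, which encodes the cell-surface proteoglycan syndecan-4, rose from 345 ± 242 to 1585 ± 215 with its brightest probe set (log2 2.42 ± 0.33, adjusted p = 0.0141), while its dimmer probe set read -0.31 and did not pass. Serpina3n, another secreted serine protease inhibitor of the acute-phase response, rose from 2515 ± 328 to 4493 ± 495 (log2 0.84 ± 0.11, adjusted p = 0.0141). Hsd11b1, the enzyme that regenerates active glucocorticoid inside cells, fell by 0.84 ± 0.09 on the log2 scale, from 5649.9 ± 227 to 3178 ± 354 (adjusted p = 0.00178). Trim14, a mediator of antiviral signalling, fell by 0.81 ± 0.11, from 1018 ± 113 to 580.2 ± 71.1 (adjusted p = 0.0141). In all 5 genes every knockout array lay beyond every wild-type array. Of the genes that did not pass, Iigp1, an interferon-induced GTPase, came nearest among the higher ones (log2 0.72 ± 0.12, adjusted p = 0.0912). It came ahead of Sbsn (0.60) and Dnajb14 (0.57, but -0.09 with its dimmer probe set). Further higher ones, on chromosome 12 like Bdkrb1, were Vcpkmt (0.98), Dtd2 (0.77) and Arf6 (0.32). The dimmer probe sets of Arf6 read 0.43, 0.12 and -0.91, and the mean of its probe sets -0.05. The lower ones were Serinc3 (log2 -0.73 ± 0.13, adjusted p = 0.174), Cdc42ep1 (-0.47, but 0.17 with that mean), Phgdh (-0.51), Fam53b (-0.84), Tmem45b (-0.78) and Gpd2 (-0.64), none of which passed.

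With limma, 5 of 12709 genes passed an adjusted p of 0.05, 3 higher and 2 lower, and 928 had an unadjusted p under 0.05 where 635 were expected. The 2 groups of arrays did not overlap in 488 genes, 3.84% of all where chance gives 2.86%. Serpina1b and Hsd11b1 stayed past the threshold in all 24 alternatives, at adjusted p up to 0.000419 and 0.0229, whereas Sdc4 passed in 13 (log2 1.06 to 2.84), Serpina3n in 17 and Trim14 in 18, with adjusted p up to 0.125 each. The count was 14 without wild-type array 1, 2 without wild-type array 3, knockout array 1 or knockout array 2, and 3 without wild-type array 4 or knockout array 4. Centring each array on its median gave 10 genes, 2 higher and 8 lower, and moved the median difference of all genes from 0.02 to -0.13. Serpina1b belongs to a family of closely similar genes, and its probe set is of a kind that can bind several of them.

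Genes of lipid storage and fuel oxidation had lower means in knockout fat as groups, although nearly all single members did not pass. All 21 measured genes of fatty acid oxidation were lower, with a median log2 difference of -0.17 (adjusted p = 6.37e-07 by camera; adjusted p = 0.378 with an estimated correlation), among them the mitochondrial beta-oxidation enzymes Hadhb (-0.32 ± 0.11) and Hadh (-0.30 ± 0.10). The median was -0.12 without wild-type array 1 and -0.11 without knockout array 4. Of 23 genes of fatty acid and triglyceride synthesis 22 were lower (median -0.27, adjusted p = 7.33e-06; adjusted p = 0.378 with an estimated correlation), with the lipogenic transcription factor Srebf1 at -0.38 ± 0.15 and Thrsp at -0.40 ± 0.17. All 17 adipocyte identity genes were lower (median -0.22, adjusted p = 8.28e-06; adjusted p = 0.378 with an estimated correlation), including the lipid droplet protein gene Cidec (-0.28 ± 0.12) and Pparg (-0.22 ± 0.10), the master regulator of adipogenesis. That median was -0.14 without wild-type array 1 or knockout array 3 and -0.10 without knockout array 4. Lipolysis and fatty acid uptake had 12 of 14 genes lower (median -0.22, adjusted p = 1.29e-05; adjusted p = 0.378 with an estimated correlation). Of these, 2 passed when adjusted over the list alone, namely the lipoprotein receptor gene Vldlr, which fell by 0.56 ± 0.15 from 1539.7 ± 299.9 to 1039 ± 187, and Mgll, the monoglyceride lipase, which fell by 0.32 ± 0.09 (adjusted p = 0.0288 each). The tricarboxylic acid cycle and pyruvate list had 19 of 20 genes lower (median -0.18, adjusted p = 7.33e-06; adjusted p = 0.378 with an estimated correlation), with Ogdh at -0.22 ± 0.08, and oxidative phosphorylation 40 of 43 (median -0.08, adjusted p = 2.35e-05; adjusted p = 0.556 with an estimated correlation). Without wild-type array 1 these medians were -0.11 and -0.05. Glycolysis had 11 of 16 genes lower (median -0.11, adjusted p = 0.00944; adjusted p = 0.378 with an estimated correlation), with Pfkl at -0.28 ± 0.10, and no longer passed without wild-type array 1 (median -0.07, adjusted p = 0.0744). Without wild-type array 4 the median was -0.16. Quantile normalization ended the calls of oxidative phosphorylation (adjusted p = 0.492) and glycolysis (0.114).

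Among markers of other cell types, endothelial genes were lower and macrophage genes higher in knockout fat. Of 18 endothelial genes 15 were lower (median -0.10, adjusted p = 0.00596; adjusted p = 0.556 with an estimated correlation), such as the water channel Aqp1 (-0.19 ± 0.09) and the VEGF receptor gene Flt1 (-0.35 ± 0.15). This call was lost without wild-type array 4 (adjusted p = 0.0929) and without knockout array 4 (0.0999, median -0.06). The median was -0.17 without knockout array 2. Of 24 macrophage genes 23 were higher (median 0.27, adjusted p = 3.65e-05; adjusted p = 0.657 with an estimated correlation), including Mpeg1 (0.76 ± 0.29), which forms pores in phagosomes, and the lysozyme gene Lyz2 (0.30 ± 0.20). The macrophage call rested on knockout array 1, without which the adjusted p was 0.449 and the median 0.06 (0.17 without wild-type array 1, 0.42 without knockout array 3), and Csf1r, one of its brightest members, differed by only 0.03 ± 0.16, which turned to -0.12 when arrays were centred on their median. Interferon response genes were higher in 17 of 19 cases (median 0.23, adjusted p = 2.41e-05; adjusted p = 0.378 with an estimated correlation), and the GTPase gene Igtp, which rose from 304 ± 44.2 to 440 ± 59.7 (log2 0.53 ± 0.13), passed when adjusted over the list alone (adjusted p = 0.0201). Immediate early and heat shock genes, which answer within minutes to stimuli and to tissue handling, were higher in 15 of 22 cases (median 0.19, or 0.08 without wild-type array 3; adjusted p = 0.00561; adjusted p = 0.378 with an estimated correlation). When adjusted over the list alone 3 of them passed: Junb rose by 0.72 ± 0.16, Egr1 by 0.68 ± 0.20 and Ier2 by 0.37 ± 0.11 (adjusted p = 0.0104, 0.0447 and 0.0447).

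With the preset correlation of 0.01, camera passed 11 of 31 lists, 3 higher and 8 lower; with an estimated correlation 0 passed, and with fry 0 passed in one direction and 4 when members could move either way. Camera on ranks passed 11. Centring arrays on their median gave 8 lists higher and 8 lower. The remaining 20 lists did not pass; the smallest adjusted p among them was 0.0729, for cell cycle genes.

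**Figure D2:**
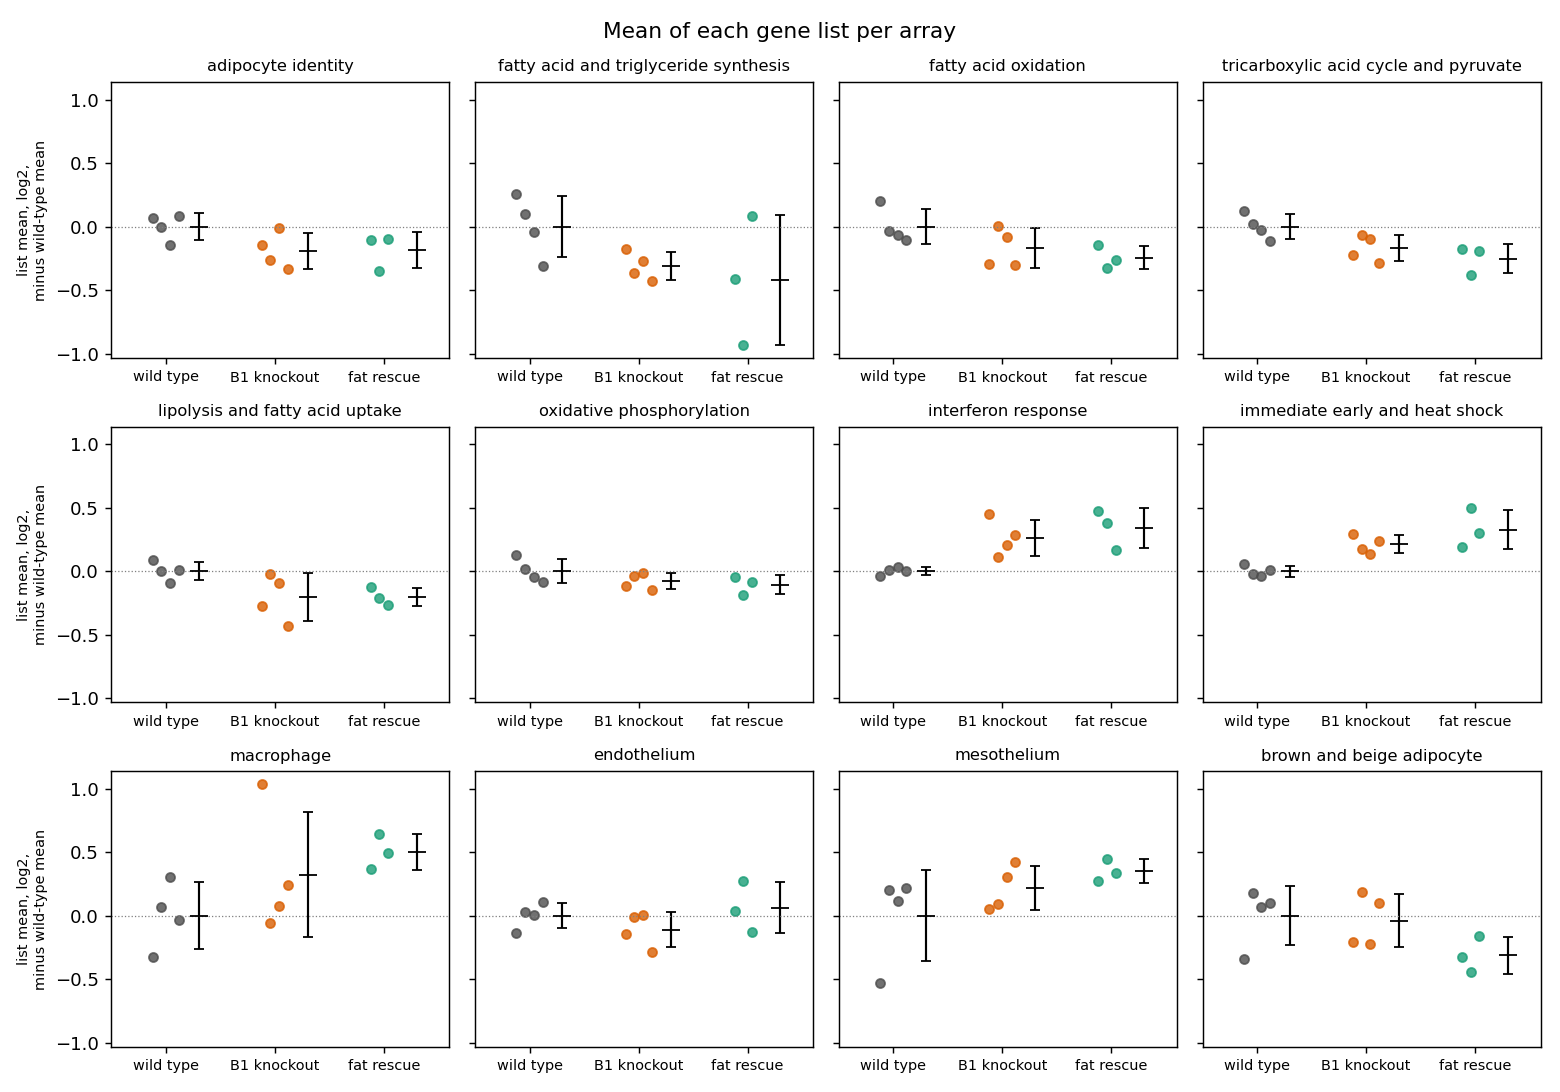
Mean log2 signal of the measured members of 12 gene lists in each array, minus the mean of the 4 wild-type arrays; points are arrays (4 wild type, 4 knockout, 3 fat rescue) and bars the mean ± SD of each genotype. Fatty acid oxidation averaged -0.17 in knockout and -0.25 in fat rescue, and interferon response 0.26 and 0.34.

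The comparison of fat rescue with knockout asks which differences return when the receptor is expressed in fat alone. No single gene passed, and the smallest adjusted p was 0.998. Mcm2, a replication licensing factor, read 191 ± 36.7 (SD, n = 4) in knockout and 80.3 ± 9.74 (n = 3) in fat rescue (log2 -1.23 ± 0.25), while its dimmer probe set read 0.28, and Serinc4 read 50.8 and 20.1, too low in fat rescue for an exact size. Neither passed. Nkain4 (0.61 ± 0.16), Smad6 (0.58), an inhibitor of BMP signalling, and the MAP kinase phosphatase gene Dusp4 (0.54) were among those with higher means that did not pass, beside Rap1gap2 (0.46), Lrsam1 (0.52) and Rapgef5 (0.36). Further lower means that did not pass were those of Sbsn (-0.46), Desi1 (-0.41, but -0.03 and 0.39 with its dimmer probe sets), Syt11 (-0.56) and Pacc1 (-0.63), of which the last pair turned to 0.19 and 0.08 with the mean of their probe sets. Hsd11b1 and Serpina1b, which differed between knockout and wild type, did not pass here. Endothelial genes were higher in 17 of 18 cases (median 0.18, adjusted p = 0.00154; adjusted p = 0.884 with an estimated correlation), with Esam at 0.24 ± 0.11 and the angiopoietin receptor gene Tek at 0.28 ± 0.14. Mesothelial genes, markers of the epithelium that covers this fat depot, were higher in 11 of 14 cases (median 0.24, adjusted p = 0.00353; adjusted p = 0.884 with an estimated correlation), with Upk1b at 0.52 ± 0.16. Adipocyte identity (adjusted p = 0.989, 10 of 17 genes higher), lipolysis and fatty acid uptake (0.944, 6 of 14 higher) and fatty acid oxidation (0.106, 15 of 21 lower) did not pass in this comparison. Fatty acid and triglyceride synthesis was lower in 17 of 23 genes and the tricarboxylic acid cycle and pyruvate list in 16 of 20, and macrophage genes were higher in 19 of 24. These 3 lists lay further from wild type than in knockout and did not pass either (camera adjusted p = 0.0721 each, 0.884 with an estimated correlation).

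With limma 0 genes passed, with 484 at an unadjusted p under 0.05 where 635 were expected, and the groups did not overlap in 627 genes, 4.93% where chance gives 5.71%. Every alternative also gave 0. Camera passed 2 of 31 lists, both higher, and fry passed 0; without rescue array 3 neither list passed (endothelium median 0.09, adjusted p = 0.241; mesothelium 0.162). The endothelial median was 0.11 without knockout array 4. By contrast, 8 lists passed without knockout array 1 and 8 without knockout array 4, 11 without rescue array 1 and 9 without rescue array 2. Camera on ranks passed 6 lists, 4 higher and 2 lower. The higher ones were endothelium, mesothelium, macrophage (adjusted p = 0.0277) and immediate early and heat shock genes. The lower ones were fatty acid and triglyceride synthesis (0.0451) and the tricarboxylic acid cycle and pyruvate list (0.0277).

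The comparison of fat rescue with wild type asks what remained different with the receptor expressed in fat only. Serpina1b rose to 527 ± 202 (n = 3; log2 4.29 ± 0.30, adjusted p = 3.80e-05; no exact size either, 2.87 to 6.17 over the alternatives) and Sdc4 to 1762 ± 187 (n = 3; log2 2.58 ± 0.35, adjusted p = 0.0398; -0.52 with its dimmer probe set), in each of the 3 rescue arrays. Serpina3n (log2 0.72 ± 0.12, adjusted p = 0.0753), Iigp1 (0.76, adjusted p = 0.0753), Vcpkmt (1.31, adjusted p = 0.0592), Dusp4 (0.80), Plk2 (0.74) and the chemokine gene Ccl5 (1.01) had higher means and did not pass over all genes. Serinc3 (log2 -0.97, adjusted p = 0.0507), Cox8b (-1.33 ± 0.20, adjusted p = 0.0507), Zfp277 (-0.70, but 0.25 with its dimmer probe set), Hsd11b1 (-0.55, adjusted p = 0.0753), Trim14 (-0.63, adjusted p = 0.150) and Itga7 (-0.50) had lower means and did not pass either. With limma 2 genes passed, both higher, and 1028 had an unadjusted p under 0.05 where 635 were expected. The groups did not overlap in 1174 genes, 9.24% where chance gives 5.71%. The count was 8 without wild-type array 1, 5 without knockout array 3, 4 without knockout array 4, and 1 without wild-type array 2, 3 or 4, knockout array 2, or rescue array 1, 2 or 3; Serpina1b passed in all 24 alternatives, Sdc4 in 12 (log2 1.03 to 3.03, adjusted p up to 0.249). Centring arrays on their median gave 5 genes, 2 higher and 3 lower.

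The metabolic lists were lower in fat rescue than in wild type as well. The ratio of the 3' to the 5' probe set of beta-actin, a sign of RNA quality, also separated these arrays, at 1.47 to 1.56 in fat rescue and 1.65 to 1.83 in wild type, while that of Gapdh overlapped. All 23 genes of fatty acid and triglyceride synthesis were lower (median -0.44, adjusted p = 1.78e-09; adjusted p = 0.283 with an estimated correlation), with Dgat1, which makes triglyceride, at -0.44 ± 0.16. The rescue arrays were uneven in this list, with means of -0.41, 0.09 and -0.94 relative to wild type (exact permutation p = 0.2), and without rescue array 3 the median was -0.19. Fatty acid oxidation had 20 of 21 genes lower (median -0.23, adjusted p = 4.32e-10; adjusted p = 0.283 with an estimated correlation), with the carnitine palmitoyltransferase gene Cpt2 at -0.47 ± 0.13. All 20 genes of the tricarboxylic acid cycle and pyruvate list were lower (median -0.24, adjusted p = 4.32e-10; adjusted p = 0.251 with an estimated correlation), and 40 of 43 genes of oxidative phosphorylation (median -0.11, adjusted p = 1.27e-07; adjusted p = 0.291 with an estimated correlation). Without rescue array 3 these medians were -0.15 and -0.06, the latter also without wild-type array 1. Adipocyte identity had 16 of 17 genes lower (median -0.12, adjusted p = 2.69e-05; adjusted p = 0.291 with an estimated correlation). Its medians were -0.23, -0.22 and -0.19 without wild-type array 2, rescue array 1 and rescue array 2. Lipolysis and fatty acid uptake had 13 of 14 lower (median -0.22, or -0.12 without rescue array 2; adjusted p = 9.52e-05; adjusted p = 0.289 with an estimated correlation), and Vldlr fell by 0.62 ± 0.16 when adjusted over the list alone (adjusted p = 0.0336). Glycolysis had 12 of 16 lower (median -0.17, adjusted p = 0.00230; adjusted p = 0.289 with an estimated correlation; median -0.10 without wild-type array 1; median -0.06 and adjusted p = 0.0571 without rescue array 3). Brown and beige adipocyte genes had 8 of 10 lower (median -0.20, adjusted p = 0.00500; adjusted p = 0.185 with an estimated correlation; 0.0536 with no filter on dim probe sets). Their median was -0.32 without wild-type array 1 and -0.09 without rescue array 3. There Cox8b, a cytochrome oxidase subunit, fell from 290.3 ± 63.3 to 114 ± 14.0 and the lipid droplet protein gene Cidea by 1.37 ± 0.38 (no exact size, with a rescue signal of 37.0), both past the threshold when adjusted over the list alone (adjusted p = 0.000159 and 0.0158).

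Immune, stress and mesothelial lists were higher in fat rescue than in wild type, between arrays whose beta-actin 3' to 5' ratios (1.47 to 1.56 and 1.65 to 1.83) did not overlap. All 19 interferon response genes were higher (median 0.31, adjusted p = 2.82e-08; adjusted p = 0.213 with an estimated correlation), and 6 passed when adjusted over the list alone, among them Igtp (0.58 ± 0.14), Ifi47 (0.61 ± 0.15) and the antiviral enzyme gene Rsad2 (0.56 ± 0.14). Of 24 macrophage genes 23 were higher (median 0.41, adjusted p = 2.82e-08; adjusted p = 0.291 with an estimated correlation), with Tyrobp at 0.76 ± 0.26 and the lysosomal protease gene Ctss at 0.96 ± 0.34. Immediate early and heat shock genes were higher in 20 of 22 cases (median 0.28, or 0.16 without rescue array 3; adjusted p = 3.48e-06; adjusted p = 0.177 with an estimated correlation). Adjusted over the list alone, 4 of them passed, namely Egr1 (0.89 ± 0.21), Ier2 (0.48 ± 0.12), Junb (0.66 ± 0.17) and Atf3 (1.08 ± 0.29). Mesothelial genes were higher in 13 of 14 cases (median 0.37, adjusted p = 2.10e-05; adjusted p = 0.289 with an estimated correlation), and Upk1b rose by 0.71 ± 0.16 when adjusted over the list alone (adjusted p = 0.0126). The median was 0.15 without wild-type array 1, whose mesothelial mean lay 0.53 below that of all 4 wild-type arrays.

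The calls of 4 further lists hung on single arrays. T and B lymphocyte genes were higher in 14 of 16 cases (median 0.47, adjusted p = 0.0383; adjusted p = 0.477 with an estimated correlation) but not past the threshold without wild-type array 1 (0.292, median 0.19) or 4 (0.0665) or rescue array 1 (0.173, median 0.31) or 2 (0.115). Of its brightest members, the immunoglobulin gene Ighm read -0.39 ± 0.39 and Jchain 0.51 ± 0.71, and both changed sign without single arrays (Ighm 0.27 without rescue array 3; Jchain -0.17 without wild-type array 1 and -0.15 without rescue array 1). Cytokines, chemokines and acute inflammation had 14 of 18 genes higher (median 0.40, adjusted p = 0.0434; adjusted p = 0.291 with an estimated correlation). That call was lost without wild-type array 1 (0.153, median 0.19), 3 (0.0690) or 4 (0.0559), knockout array 4 (0.0507) or rescue array 2 (0.207) or 3 (0.0769). In that list Ccl5 rose and the acute-phase gene Orm1 fell by 1.35 ± 0.32 when adjusted over the list alone (adjusted p = 0.00250 and 0.00897). All 4 measured erythroid genes were lower (median -0.51, adjusted p = 0.0167; adjusted p = 0.291 with an estimated correlation), and the call was lost without wild-type array 1 (0.153, median -0.31) or rescue array 2 (0.116, median -0.20). Cytosolic ribosomal protein genes were higher in 22 of 23 cases (median 0.08, adjusted p = 0.0383; adjusted p = 0.583 with an estimated correlation), but the median turned to -0.02 when arrays were centred on their median. The ribosomal call was lost without wild-type array 1 (0.285, median 0.04) or 3 (0.0579) or rescue array 1 (0.148) or 2 (0.107).

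Camera passed 16 of 31 lists, 7 higher and 9 lower, with the preset correlation and 0 with an estimated one; fry passed 1 list in one direction, the immediate early and heat shock genes (adjusted p = 0.0321), and 5 when members could move either way. Camera on ranks passed 16.

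The 2 genes that passed in both comparisons against wild type, Serpina1b and Sdc4, were higher in both. Because both comparisons share the wild-type arrays, the expected overlap was also simulated with no effect. With independent genes this gave 0 shared genes on average in 100 simulations. Without any effect hardly any gene passes in either comparison, so this outcome was nearly fixed in advance. It does not show how much the shared wild-type arrays add to the overlap. With the wild-type arrays divided between the comparisons 1 gene was shared in each of 6 divisions. The moderated F test over the 3 genotypes passed 5 genes, namely Serpina1b, Sdc4, Serpina3n, Hsd11b1 and Trim14, with 815 genes at an unadjusted p under 0.05. That count was 1 without wild-type array 3 or 4, 2 without wild-type array 2, knockout array 2 or 4, or rescue array 1 or 2, and 3 without rescue array 3. Differences between knockout and wild type and differences between fat rescue and knockout, taken from separate knockout arrays, correlated across the 12709 genes with a Pearson r of -0.133. Simulations of independent genes without effect gave -0.0377 to 0.0371. Genes in the arrays are not independent, so this r has no p-value and the simulated range is too narrow to judge it by. Over the 6 divisions r ran from -0.233 to -0.0193. The mean r was 0.00703 without rescue array 1 and -0.250 without knockout array 1. Of the 200 genes that differed most between knockout and wild type, a mean of 52.7% had the opposite sign in fat rescue against the other knockout arrays, between 31.5% and 63.5% over the 6 divisions of the knockout arrays.

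Bdkrb1 lies on chromosome 12 of the mouse assembly GRCm38.p6, where 13 protein-coding genes lie between it and Serpina3n and 31 between it and Serpina1b. Of 61 listed neighbours 36 were measured. Serpina1b and Serpina3n passed among them in knockout against wild type over all genes, and adjusted over the list alone Clmn, which encodes calmin, also fell in knockout (by 0.63) and in fat rescue (by 0.73) against wild type. The neighbours did not shift together in one direction (camera adjusted p = 0.370 in knockout and 0.127 in fat rescue against wild type), but they differed when either direction counted (fry mixed adjusted p = 4.19e-09 and 1.97e-08). Between fat rescue and knockout they did not (fry mixed adjusted p = 0.935). The difference from wild type rested largely on Serpina1b and Serpina3n. Without them the mean squared z of the other 34 genes stood at percentiles 85.3 in knockout and 86.8 in fat rescue among random lists, which kept their own highest genes. The 8 measured genes of kinin receptors and kinin metabolism did not pass as a list in any comparison (adjusted p = 0.731, 0.566 and 0.497), although the kinin-degrading peptidase gene Mme fell by 0.60 ± 0.14 in fat rescue against wild type when adjusted over the list alone (adjusted p = 0.00837).

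**Figure D3:**
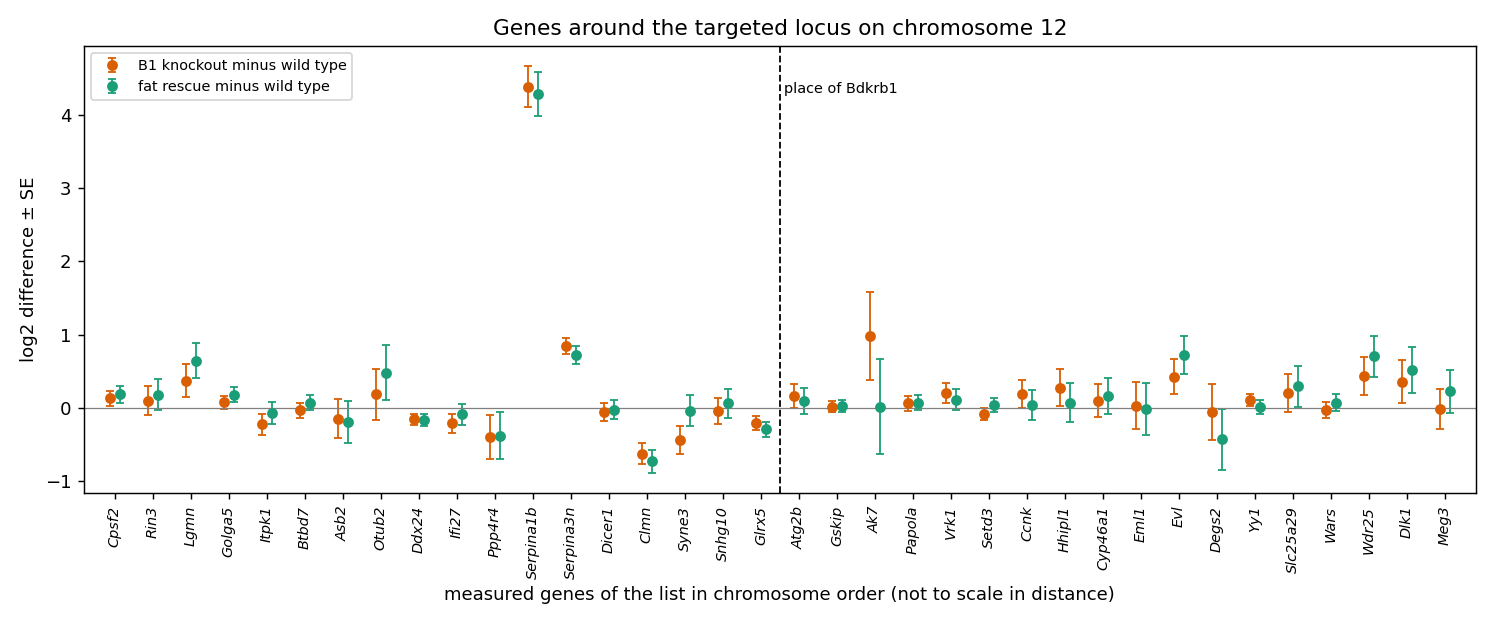
Log2 difference (± SE) of the 36 measured neighbours of Bdkrb1 on chromosome 12, in gene order, for knockout and fat rescue minus wild type; the dashed line marks the place of Bdkrb1. Serpina1b stands at 4.39 and 4.29 and Serpina3n at 0.84 and 0.72.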

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

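The tests of linked DNA at chromosome 12 and of fewer adipocytes, the fit without wild-type array 1 and rescue array 1, and everything that sets both lines together against wild type, were chosen only after the result was seen.

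In 13 of 324 groups of 4 arrays 1 array lay apart from the other 3 by more than Dixon's limit for the gap divided by the range; chance gives about 1 in 20, or 16.2. Wild-type array 1 was the array apart in 3 of them: Nkain4 (gap ratio 0.936, signal 189 against 256 to 262), the mean of the mesothelial list (0.862, -0.71 against -0.07 to 0.04, where list means are relative to the mean of the other 3 arrays) and that of the adipose progenitor and fibroblast list (0.853, -0.59). Knockout array 1 stood apart in Cd53 (0.891, signal 1257 against 661 to 708), Mpeg1 (0.836, 2081 against 699 to 836) and the mean of the extracellular matrix list (0.834, 0.74). Among wild-type arrays, array 4 was apart in Smad6 (0.885), and array 2 in Tyrobp (0.871) and Lipe (0.835). Among knockout arrays, array 3 was apart in Zfp277 (0.873), array 2 in Mcm2 (0.849) and Nr4a1 (0.830), and array 4 in Ldha (0.836).

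Neighbours of Bdkrb1 on chromosome 12 differed from wild type in both lines that lack the endogenous receptor. Against random lists of 36 genes their mean squared z stood at the 99.99th percentile in knockout and in fat rescue against wild type, and at percentile 5.54 between fat rescue and knockout, which share the targeted locus. The mean squared z of the list was also divided by that of all genes, in each of 35 splits of the 8 arrays. Only the split by genotype itself gave a ratio as high (2.495, against 1.53 in the highest other split). This is the smallest share that 35 splits can give, so chance is less likely but cannot be excluded. With the adipocyte and macrophage list means as covariates the percentile was 99.95. This percentile includes Serpina1b and Serpina3n and was not computed without them. It therefore cannot decide whether a changed share of these cells lies behind the differences of the other neighbours. Other cell types were not covered by these covariates. Stem-cell DNA that came along with the targeted locus is a candidate explanation that stays open. The signal of this list rests largely on Serpina1b and Serpina3n. Without them the percentiles were 85.3 in knockout and 86.8 in fat rescue against wild type and 6.47 between fat rescue and knockout. The random lists kept their highest genes, so these percentiles may be too low. Over the whole chromosome, 11 of 58 genes with an unadjusted limma p under 0.001 in both lines against wild type lay on chromosome 12, where 2.05 were expected. Clmn and Vcpkmt were among these 11, and genes on a chromosome are not independent. A biological effect of the receptor's absence outside fat cells, which both lines share, was not tested and stays open.

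Sdc4 and Serinc3, with 23 protein-coding genes between them on chromosome 2, differed from wild type in both lines together (log2 2.49 ± 0.28 and -0.84 ± 0.13). In both genes wild-type array 1 lay nearest to the lines, with Sdc4 at 696.5 against 177 to 313 in the other 3 wild-type arrays and Serinc3 at 4590.0 against 5935 to 6815. A changed share of adipocytes or macrophages is argued against. With their list means as covariates the differences were 2.99 ± 0.34 and -1.02 ± 0.16, and the larger unadjusted limma p was 3.05e-05. Adjusted over all genes, the limma p was 0.0114 for Sdc4 and 0.0969 for Serinc3, which no longer passed. Other cell types were not covered by these covariates. Linked DNA around Sdc4 cannot be told apart from other causes. The 20 measured genes nearest to Sdc4 stood at percentile 70.1 of all such windows (mean squared z 1.57). But this window left out Sdc4 and Serinc3, which passed, and Gm16316, which did not (adjusted p = 0.168). All other windows kept every gene, so the percentile does not compare like with like. The windows of Rims4 and Tomm34, which lie in this stretch, reached 4.67 and 4.64. Without wild-type array 1 and rescue array 1, Gm16316 passed in knockout (0.0396) and Pkig, also on chromosome 2, in fat rescue (0.0480) against wild type. Linked DNA need not change most genes on it, so the bound of 95 set beforehand was wrong. A sequence variant under single probes may still lie behind Sdc4, whose other probe set read -0.31 and -0.52 against wild type, and neither this nor a biological effect of the receptor was tested.

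With camera's preset correlation metabolic lists were lower and the macrophage list higher in knockout fat than in wild type, but with an estimated correlation 0 of 31 lists passed, and without knockout array 1 the macrophage list did not (adjusted p = 0.449, median 0.06). Without wild-type array 1, 10 of the 11 lists still passed in the same direction with the preset correlation, so most calls did not need that array. Medians shrank, to -0.05 instead of -0.08 for oxidative phosphorylation, -0.11 instead of -0.18 for the tricarboxylic acid cycle and 0.17 instead of 0.27 for macrophages. Other splits of the 8 arrays passed a median of 8.5 lists and up to 18 in the same test. A count of passing lists therefore cannot decide whether single arrays lie behind these shifts. A smaller share of adipocytes would raise the markers of all other cell types alike, and the macrophage mean minus the endothelial mean differed from wild type by 0.44 (exact permutation p = 0.2, n = 4 and 4; 0.44 and exact permutation p = 0.0571 in fat rescue). This share cannot be told apart from other causes, since the p allows it while the endothelial mean was lower than in wild type, a condition spelled out only after the p was known, and the arrays are too few. An effect of the receptor on adipocytes or macrophages was not tested.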

How the results depend on the processing

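The fit without wild-type array 1 and rescue array 1, median centring of the lists and all settings of both lines against wild type were chosen only after the result was seen. Of counts over all alternatives 132 stayed within 1.5 times and 62 did not; of list results 652 kept direction and side of the threshold, 100 lost the threshold and 1 reversed; of named genes 4041 kept both, 47 passed newly, 42 lost the threshold and 21 reversed. Except where named, the cause was not tested. Signals near background, such as those of Bdkrb1, are the least certain, and fat rescue against knockout gave 0 genes in every alternative (0 to 0 without single arrays).

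Genes of knockout against wild type (5) were 10 with median centring, 2 without trend, 2 with only the groups compared, 14 without both arrays, and 2 to 14 without single arrays. With probe sets tested singly 8 probe sets passed, which held 5 genes and 2 probe sets without a single gene symbol. Genes of fat rescue against wild type (2) were 5 with median centring, 6 with the upper 40% of probe sets, 1 each with the mean of probe sets, without trend, with robust eBayes and with only the groups compared, 7 with array weights, 6 without both arrays, and 1 to 8 without single arrays. With probe sets singly 6 probe sets passed, which held 3 genes and 2 probe sets without a single gene symbol. The F test (5) gave 2 with the mean of probe sets, 1 without trend and 1 to 7 without single arrays. Both lines against wild type (8) gave 14 with median centring, 2 without trend, 14 without both arrays and 4 to 21 without single arrays. With probe sets singly 15 passed there, a count of probe sets and not of genes. With fewer arrays or more tests the threshold also moves.

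Lists of knockout against wild type (11) were 0 with an estimated correlation and 0 with fry, and 10 to 14 without single arrays. Those of fat rescue against knockout (2) were 0 with an estimated correlation, 6 on ranks, 0 with fry, 11 without both arrays and 0 to 11 without single arrays. Among the 11 without both arrays, fatty acid synthesis, fatty acid oxidation, oxidative phosphorylation and the tricarboxylic acid cycle were lower than in knockout. Macrophage, endothelial and mesothelial genes were higher. Those of fat rescue against wild type (16) were 0 with an estimated correlation, 1 with fry, and 12 to 16 without single arrays. Cytosolic ribosomal proteins turned to -0.022 with median centring.

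Bdkrb1 against knockout (2.28) passed with median centring (2.33), log2(value + 50) (0.77), robust eBayes (2.28) and only the groups compared (2.28), and ranged from 1.80 to 2.68 without single arrays. Against wild type (2.86) it lost the threshold without trend (2.86) and without both arrays (2.53), and ranged from 2.45 to 3.49. Equal replicate numbers marked no pairing that held throughout: residuals of 4 of 10 pairs correlated above 0.1, among them all 3 pairs of number 1 (0.14, 0.35 and 0.19), the lowest was -0.14, and 5 of 11 arrays correlated best with their own number. With the replicate block the counts were 8 genes in knockout against wild type, 2 in the F test and 6 lists in fat rescue against knockout, and Bdkrb1 read 2.49 against knockout and passed.

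With the mean of a gene's probe sets, Arf6 (-0.055) and Cdc42ep1 (0.17) in knockout against wild type, Syt11 (0.19) and Pacc1 (0.084) in fat rescue against knockout, and Ogdh (0.081) and Ighm (0.44) in fat rescue against wild type reversed. In knockout against wild type Csf1r reversed with median centring (-0.12), array weights (-0.0041) and without both arrays (-0.023). In fat rescue against wild type Cldn15 reversed with median centring (-0.071) and without both arrays (-0.099), and Jchain without both (-0.82). Without single arrays the signs of 6 genes turned: in knockout against wild type Csf1r ranged from -0.11 to 0.14, Ramp2 from -0.18 to 0.017 and Eng from -0.18 to 0.029, and in fat rescue against wild type Ighm from -0.75 to 0.27, Jchain from -0.17 to 1.17 and Cldn15 from -0.10 to 0.16. The correlation of knockout and rescue effects turned to 0.0068 without both arrays and ranged from -0.250 to 0.00703 without single arrays.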

Other observations

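The fit of both lines together against wild type, the count by chromosome and the description of single probe sets were chosen only after the result was seen.

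Adipokine genes did not pass as a list in knockout against wild type (adjusted p = 0.104), but 3 of 13 passed when adjusted over the list alone. The chemerin gene Rarres2 fell by 0.45 ± 0.11, the retinol carrier gene Rbp4 by 0.43 ± 0.11 and Nrg4 by 0.47 ± 0.16 (adjusted p = 0.0130, 0.0130 and 0.0485). In fat rescue against wild type Rbp4 fell by 0.50 ± 0.12 (adjusted p = 0.0144) and Nrg4 read -0.54 ± 0.17 (adjusted p = 0.0516). Dpt, a dermatopontin gene of fibroblasts, fell by 0.49 ± 0.12 in fat rescue against wild type when adjusted over its list alone (adjusted p = 0.0228) and read -0.36 ± 0.11 in knockout (adjusted p = 0.106). The cold-responsive gene Cox8b fell by 0.70 ± 0.18 in knockout against wild type over the brown and beige adipocyte list alone (adjusted p = 0.0211).

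With the 7 arrays of both lines set against the 4 wild-type arrays, 8 genes passed in limma. Serpina1b rose by 4.34 (no exact size, given its low wild-type signal), Sdc4 by 2.49, Vcpkmt, a lysine methyltransferase gene, by 1.13 (adjusted p = 0.0341), Serpina3n by 0.79 and Iigp1 by 0.74 (adjusted p = 0.0108). Serinc3 fell by 0.84 (adjusted p = 0.0205), Trim14 fell by 0.73 and Hsd11b1 fell by 0.71 (adjusted p = 0.0108 each). The count was 21 without wild-type array 1 and 4 without wild-type array 3, and 14 (3 higher, 11 lower) with arrays centred on their median. Of 58 genes with an unadjusted p under 0.001 in this fit, 11 lay on chromosome 12, where 2.05 were expected (one-sided exact hypergeometric p = 4.89e-06, adjusted over chromosomes 9.79e-05; genes on a chromosome are not independent). Among them were Vcpkmt, Arf6, Dtd2 and Zfp277, with 309, 311, 379 and 398 protein-coding genes between each and Bdkrb1.

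Other splits of the arrays set the size of these counts. For knockout against wild type, 1 of 35 splits, that by genotype itself, gave as many genes as the 5 of the genotypes (highest other 1). This is the smallest share that 35 splits can give, so chance is less likely but cannot be excluded. As many lists as the 11 came from 11 of 35 splits (highest other 18), so chance cannot be excluded for the lists either. For fat rescue against knockout 35 of 35 splits gave at least 2 lists (highest other 17), so chance cannot be excluded for these. With 0 genes in that comparison the count of splits, 35 of 35 (highest other 4), was fixed in advance and decides nothing. For fat rescue against wild type 5 of 35 splits gave at least 2 genes (highest other 39, in the split that sets wild-type arrays 1 and 2 with rescue array 1) and 2 of 35 at least 16 lists (highest other 16), so chance cannot be excluded for either. The split with 39 genes points to a structure of the samples that the genotypes do not describe. Of 100 splits drawn for the moderated F test 6 gave at least 5 genes (highest other 136), so chance cannot be excluded. Of 100 for both lines against wild type 3, the grouping by genotype among them, gave at least 8 (highest other 116). That makes chance less likely but does not exclude it, since this comparison was chosen only after the result was seen. The splits with 136 and 116 genes likewise point to such a structure.

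Both probe sets of Serpina1b were higher in the lines; the second read 1.2 to 4.7 in wild type, which is background, so that no size can be given for its difference. Of probe sets without a gene symbol, 1 was higher (log2 1.03, adjusted p = 0.00585 in knockout; 1.17, adjusted p = 0.00561 in fat rescue) and another lower (-1.32, adjusted p = 0.00148; -1.02, adjusted p = 0.0436) against wild type; these were picked because no other unnamed probe sets passed in both, and what they measure is not given.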
